A study of Saccharomyces cerevisiae with 64 samples.

How the data were processed

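Polyadenylated RNA of S. cerevisiae S288c was sequenced by the authors at 32 conditions with 2 replicates each, 64 samples in all, and the 24 samples of wild type without overexpression and with IME1 were re-used from another series, per the labels. The submitters' processing notes name BWA, DESeq2 and the build sacCer3, without saying what each was used for; how reads were counted, the annotation and any shrinkage of the ratios are not given in the sources used here. The single deposited table held 1 column per condition, in log2 ratios made by the authors, with values for 6660 genes and 4 further lines that were empty and left out. The base of the logarithm is not stated in the header and was taken as 2. The values do not give a read count or a level, so the depth per sample, and the precision it gives, is unknown.

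The reference of each column was worked out from the values. In 27 columns the deposited ratios were to wild type without overexpression at 0 h, whose own column was 0 for every gene. A blank was read as no reads in either the condition or its reference. Of the values of 160 genes blank in at least 1 of the wild-type columns without overexpression at 2 to 12 h, 0 of 401 were negative in the columns of the other arms, whereas 31 of 102 were negative in the kfc1 columns without overexpression at 2 to 12 h. Of the values of 165 genes blank in at least 1 of those 5 kfc1 columns, 17 of 17 were negative in kfc1 at 0 h, and 0 of 84 were negative where the same genes did have a value in the 5 columns. Those 5 columns were therefore read as ratios to kfc1 at 0 h, and the kfc1 value at 0 h was added to put them on the scale of the others. The smallest values of genes without reads in the reference differed between columns. They ran from 0.017 (kfc1 without overexpression, 0 h) to 0.316 (kfc1 with IME1 and RIM4, 24 h). Ratios shrunken toward 0 would also give this, so genes with few reads are not strictly comparable between columns. Shrinkage that differed between columns could also bear on other genes, on counts compared between arms and on the 5 re-referenced columns.

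The analysis had been planned before the data were examined for normalized values of each replicate, with a linear model and tests. The table holds combined ratios instead, so no test was run and no p-value is given. In place of a test, a gene was counted as higher or lower when the mean of its log2 difference over the time points of a comparison was at least 1 and its sign was the same at each time point; for comparisons at a single time the size alone counted. There were 21 comparisons: kfc1 against wild type within each arm, at 0 h and over the later time points; the later time points against 0 h in each strain and arm; overexpression against none; RIM4 with IME1 against IME1 at 12 h; and the differences between these. The ranges given run from the lowest to the highest time point and are not replicate errors.

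The genes named were chosen by a rule from the same plan: the 8 highest and 8 lowest of each comparison, up to 4 members of each gene list with the largest differences, and IME1, IME2, NDT80, RIM4, RME1, IME4, MUM2, SLZ1, KAR4, PHO92 and VIR1 in every case. The rule had also asked for a minimum level, which ratios cannot give, so that part was dropped. Genes outside that rule were added after the values had been seen and only as marker genes (URA3 and LEU2) or as genes with opposite genotype differences in 2 arms (FIT2, RGI2, SPG1 and SCW10). Of the 20 gene lists fixed beforehand, 19 had measured members; the mitochondrially encoded list had none, and IRT1 of the meiotic entry list was not in the table. The ribosomal protein list was drawn by name and took in RPP1, a subunit of RNase P, which is not a ribosomal protein. Each list's median was placed among the medians of 10000 random lists of as many genes. These could not be matched for expression level, since the table has none. Their genes were drawn independently, so a percentile does not measure the uncertainty of the median of a list whose members move together. Symbols and coordinates came from the RefSeq annotation of the R64 assembly, which is the assembly behind sacCer3; 5986 of the identifiers were in it and 674 were not, and the latter kept the name in the table.

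Alternatives were chosen after the data had been seen: columns centred on their mean (column means ran from -0.160 to 0.176), genes in the RefSeq table only, genes with few reads left out (139 genes that shared an exact value with another gene), no same-sign rule, each time point left out, the kfc1 columns as deposited, and other starts for the IME1 arm, either wild type without overexpression at 0 h as the start of wild type alone (kfc1 keeping its own) or 0 h without overexpression of the same genotype in both. The rule was tested on simulated data for 1 comparison: of genes simulated with a 2-fold difference 37.3% were counted, with a 4-fold difference 100%, and with an 8-fold difference 98.5%, and 4 of 6460 genes without a difference were counted wrongly. The simulated libraries were independent draws with an assumed spread and differences constant over time, without an effect of series or shrinkage. The deposited ratios may depart from each of these settings, so the simulated rates need not hold for them. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots matplotlib 3.10.9.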

Results

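Gene expression was measured by sequencing of polyadenylated RNA from Saccharomyces cerevisiae cells under sporulation conditions, in which starved diploid yeast enters meiosis and forms spores. The 64 samples fell into 32 groups of 2 replicates, each group being a genotype (wild type or the kfc1 mutant), an overexpression arm and a time point. Without overexpression and with IME1 overexpression, both genotypes were sampled at 0, 2, 4, 6, 8 and 12 h. With IME1 and RIM4 overexpressed together they were sampled at 0, 12, 24 and 48 h. IME1 encodes the transcription factor that starts the meiotic programme, and RIM4 encodes an RNA-binding protein needed for meiosis. The 24 wild-type samples without overexpression and with IME1 were re-used from another series, per the labels, so genotype and series of origin coincided in those arms and not in the arm with IME1 and RIM4. The authors' table held 1 log2 ratio per gene and group for 6660 genes, with the replicates already combined, so no error or test could be given for any value and the depth of each sample is unknown. All values are log2 ratios to wild type without overexpression at 0 h unless stated otherwise. The base of the logarithm is not given in the table and was taken as 2. A gene was counted as higher or lower when its mean difference over the time points was at least 1 log2 unit (2-fold) and had the same sign at each of them. Ranges in parentheses run over time points.

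The deleted gene was taken from the literature to be VIR1 (YGL036W), which encodes a subunit of the complex that methylates messenger RNA at N6-adenosine (m6A). VIR1 lies on chromosome VII from 428601 to 431330 in the S. cerevisiae R64 assembly, with 1 coding exon. Its transcript was lower in kfc1 than in wild type by the same rule in each arm, with mean log2 differences of -5.74 (-6.55 to -5.25) without overexpression, -8.49 (-8.85 to -8.20) with IME1 and -10.96 (-11.31 to -10.45) with IME1 and RIM4. Of the other named genes of the m6A methyltransferase complex and reader list, the reader gene PHO92 differed most without overexpression, with a mean of 0.60 (-0.21 to 2.17, the highest at 2 h). The means there were 0.05 for IME4 (the catalytic subunit), -0.14 for MUM2, -0.33 for KAR4 and -0.46 for SLZ1. As deposited, VIR1 in kfc1 without overexpression stood between 0.00 and 1.03 at 2 to 12 h, because those 5 columns were ratios to kfc1 at 0 h; the kfc1 value at 0 h was added to them throughout. The sizes of the VIR1 differences rest on the few reads a deleted gene can give and were not compared between arms.

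**Figure D1:**
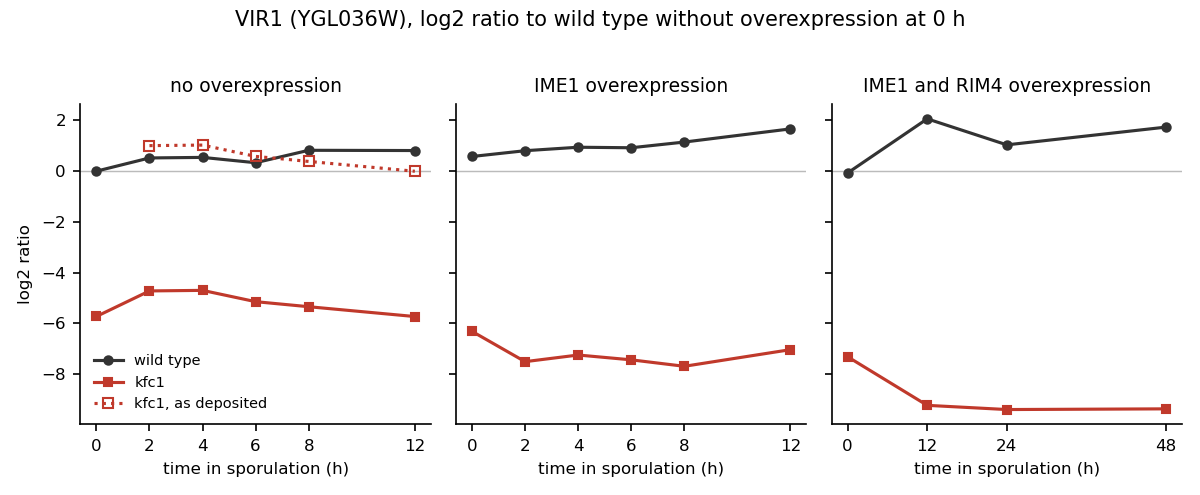
Log2 ratio of VIR1 to wild type without overexpression at 0 h (vertical axis) against hours in sporulation, in wild type (circles) and kfc1 (filled squares) for each overexpression arm, 1 value per group with replicates combined by the authors. Open squares show the 5 kfc1 values as deposited, which lie between 0.00 and 1.03, whereas the kfc1 mean difference from wild type after re-referencing was -5.74.

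At 0 h the genotypes were compared to see how far they differed at the start. Without overexpression, kfc1 had higher transcripts of the mitotic G1/S and budding genes (median difference 0.58, 4 of 32 higher, none lower), including the G1 cyclin genes PCL1 (1.53) and CLN1 (1.21), and of the polyamine exporter gene TPO2 (2.13). Lower were the heat shock gene SSA3 (-2.18), the cell wall gene PIR3 (-2.26) and the citrate synthase gene CIT3 (-1.81), with 7 of 38 stress response genes lower and none higher. With IME1, cytosolic ribosomal protein genes were higher in kfc1 (121 of 139, median 1.51), as were ribosome biogenesis genes (43 of 65, median 1.19) such as NOP1 (1.65) and DNA replication genes (20 of 36, median 1.06) such as RNR1 (2.64) and POL30 (2.62). With IME1 and RIM4 the same lists leaned the other way, with 34 of 139 ribosomal protein genes lower (median -0.79) and 6 of 65 ribosome biogenesis genes lower (median -0.78). The peptide transporter gene PTR2 was 4.07 higher with IME1 and -3.24 with IME1 and RIM4. At 0 h, 33 genes were higher and 74 lower without overexpression, 696 and 121 with IME1 (552 and 184 with each column centred on its mean), and 24 and 154 with IME1 and RIM4. The wild-type IME1 group itself stood apart at 0 h: its median for the ribosomal protein list was -2.73, against -1.25 for kfc1 with IME1, and the spread of its values over genes was 0.937 (SD), against 0.344 to 0.675 in the other groups at 0 h.

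Over time in sporulation medium without overexpression, both genotypes had higher transcripts of genes for nitrogen scavenging, amino acid synthesis and early meiosis than at 0 h. In wild type, the ammonium permease gene MEP2 was 4.22 (3.51 to 5.23) above 0 h, the general amino acid permease gene GAP1 2.94 and the GABA permease gene UGA4 2.61, with 15 of 29 nitrogen catabolite repression targets higher and 2 lower. Of the amino acid biosynthesis genes 25 of 53 were higher, and 12 of 35 early meiotic genes were higher, including the recombination genes MND1 (2.49) and SAE3 (2.47). The mitotic G1/S and budding list was lower (15 of 32, median -0.80), with EGT2 at -2.36 and DSE1 at -2.27, as were 5 of 34 cell wall and secretory genes such as CCW12 (-1.93). The serine and threonine deaminase gene CHA1 had the lowest mean, -4.13. The middle meiotic list, which the transcription factor Ndt80 turns on as cells commit to division, stayed near 0 h with a median of 0.17, and NDT80 itself averaged 0.21.

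In kfc1 over the same hours, MEP2 was 6.97 (6.26 to 8.55) above kfc1 at 0 h, the GATA repressor gene DAL80 6.56, GAP1 5.65 and UGA4 5.08, and 19 of 29 nitrogen catabolite repression targets were higher. Amino acid biosynthesis genes were higher in 33 of 53 cases, with ARG1 at 3.91 and HOM3 at 3.37, and 16 of 35 early meiotic genes were higher, with SAE3 at 3.11 and MND1 at 2.42. The respiratory chain and ATP synthase list was lower (8 of 33, median -0.71), with ATP5 at -1.19, and cytosolic ribosomal protein genes had a median of -0.82, with 35 of 139 lower or 4 of 139 without the 2 h group. In all, 446 genes were higher and 267 lower over time in kfc1, against 154 and 84 in wild type. With the 5 kfc1 columns taken as deposited the kfc1 count over time was 1257, because the kfc1 value at 0 h is then subtracted a second time.

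The change over time differed between the genotypes most in nitrogen genes. Relative to the change in wild type, DAL80 was 4.01 (2.54 to 4.69) higher in kfc1, the allantoin permease gene DAL4 2.76, MEP2 2.75 and GAP1 2.71, with 17 of 29 nitrogen catabolite repression targets higher and none lower. Genes of the TCA and glyoxylate cycles were higher too (11 of 31), with CIT3 at 2.30 and the acetate transporter gene ADY2 at 2.23; both started lower in kfc1 at 0 h. The hexose transporter genes HXT6 (-2.39) and HXT7 (-1.46) and the polyamine exporter gene TPO2 (-2.95) were lower. TPO2 had started higher in kfc1 at 0 h, by the value given above, which enters its change. For this difference 206 genes were higher and 43 lower.

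Without overexpression, the direct comparison of kfc1 with wild type at 2 to 12 h asked what the loss of the gene changed in starved cells. Nitrogen catabolite repression targets, which encode permeases and enzymes for poor nitrogen sources, were higher in kfc1: 18 of 29 by the rule and none lower, with a median difference of 1.57 that lay at percentile 100 of 10000 random lists of the same size. DAL80 was 3.32 (1.85 to 4.00) higher, DAL4 3.14 (2.24 to 3.69), MEP2 2.78 (1.11 to 4.44) and the allantoate permease gene DAL5 2.54 (1.54 to 3.81). The median difference of the list was 2.54 at 2 h, 2.00 at 4 h, 1.79 at 6 h, 0.91 at 8 h and 0.71 at 12 h. Amino acid biosynthesis genes were higher in 6 of 53 cases (3 without the 2 h groups), with the arginine gene ARG3 at 1.42. Cytosolic ribosomal protein genes were lower (median -0.58), among them RPL9B (-1.20) and RPS9A (-1.10), although only 4 of 139 met the rule, or 8 without the 6 h and 9 without the 12 h groups. Their difference was largest at 2 h, with a median of -1.26 and 103 of 139 at least 2-fold lower. It was -0.78 at 4 h (20 lower) and -0.20 at 12 h (2 lower). The stress genes HSP26 (-1.43) and HSP30 (-1.35) and the thiamine gene THI4 (-1.32) were lower, with 5 of 38 stress response genes lower (3 without the 6 h or without the 8 h groups). 

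The meiotic lists differed less between the genotypes in this arm than the nitrogen genes. The early meiotic list had a median difference of -0.11 with HOP2 alone lower (-1.20), the middle list 0.15 with none higher or lower by the rule, and the late sporulation list 0.09 with SGA1 higher (1.14) and SPS100 lower (-1.30). The middle list's median, small as it was, lay at percentile 99.96 of the random lists, with 33 of 45 genes above 0. Random lists draw genes independently, so this percentile makes no allowance for members that move together. The list's difference was 0.45 at 2 h, where 6 genes were at least 2-fold higher, 0.30 at 4 h and -0.11 at 12 h. Of the regulators, RIM4 was lower in kfc1 at each time point without reaching the rule (-0.84, -1.41 to -0.25), and IME1 averaged -0.55 with -1.31 at 2 h and 0.22 at 6 h. IME2 (-0.29) and NDT80 (-0.07) did not reach the rule either. In all, 93 genes were higher and 24 lower, a total of 117 that was 177 without the 12 h groups. Per time point, 322 genes were at least 2-fold higher and 300 lower at 2 h, and 43 higher and 19 lower at 12 h. Apart from nitrogen and ribosomal protein genes, list medians lay between -0.39 (glycolysis and hexose transport) and 0.38 (amino acid biosynthesis). Wild type came from another series here, so series of origin cannot be separated from genotype within this arm.

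**Figure D2:**
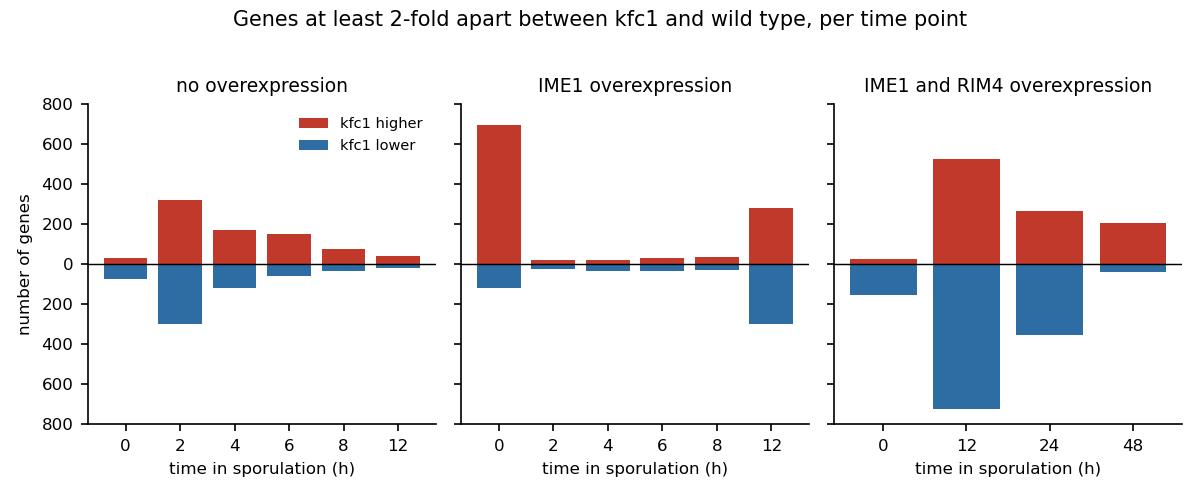
Number of genes at least 2-fold higher (up) or lower (down) in kfc1 than in wild type at each hour in sporulation, per overexpression arm, without any rule across time points. Without overexpression the largest numbers were at 2 h (322 and 300), with IME1 at 0 h (696 and 121), and with IME1 and RIM4 at 12 h (525 and 724).

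Arms with and without IME1 overexpression were compared to see which transcripts differed between them in each genotype. In both genotypes the early meiotic genes, which encode the recombination and synaptonemal complex machinery, were higher with IME1 than without it at 2 to 12 h. In wild type 30 of 35 were higher (median 2.30), with MEI5 at 5.12 (4.21 to 6.16), the telomere protein gene NDJ1 at 3.83 and ECM11 at 3.82. In kfc1 29 of 35 were higher (median 2.59), with MEI5 at 4.95 (3.57 to 6.44), HOP2 at 4.74 and the kinase gene MEK1 at 4.14. IME1 itself was higher by 2.84 in wild type and 3.28 in kfc1, IME2, a kinase gene and IME1 target, by 3.03 and 3.13, and RIM4 by 2.24 and 2.68. The middle meiotic genes were higher in 15 of 45 cases in wild type (7 without the 12 h groups) and in 5 of 45 in kfc1. Glycolysis and hexose transport genes were lower in both, 13 of 27 in wild type and 11 of 27 in kfc1, with TDH2 at -1.69 and -1.58. Stress response genes were lower in 19 of 38 cases in wild type, with SIP18 at -4.03, and in 7 of 38 in kfc1, with SIP18 at -2.07. In kfc1, 10 of 29 nitrogen catabolite repression targets were lower with IME1 than without it (17 without the 12 h groups), with MEP2 at -3.23 and DAL4 at -3.03. In all, 395 genes were higher and 258 lower in wild type, and 263 and 184 in kfc1. The arms also differed in marker genes. At 2 to 12 h with IME1, URA3 stood between 6.90 and 7.50 in wild type and between 6.72 and 8.25 in kfc1. LEU2 stood between 6.87 and 7.48 in wild type with IME1. Without overexpression both markers were near 0 or had no value. URA3 in both genotypes, and LEU2 in wild type, therefore cannot be separated from IME1 in these differences.

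The responses to IME1 differed between the genotypes in the nitrogen genes, among others, and little in the early meiotic genes. For the nitrogen list this restates the genotype difference without overexpression, which was nearly absent with IME1. At 2 h, for example, its median genotype difference was 2.54 without overexpression and -0.09 with IME1. For 16 of 29 nitrogen catabolite repression targets the response was lower in kfc1 (median -1.60), with DAL80 at -3.32 and MEP2 at -3.29, whereas the early meiotic list had a median of 0.05 with only HOP2 (1.19) differing by the rule. The response of 11 of 53 amino acid biosynthesis genes was also lower, with ARG1 at -2.32, and that of 9 of 38 stress response genes higher, with GRE1 at 2.64 and CTT1, the cytosolic catalase gene, at 1.91. Middle meiotic genes responded less in kfc1 in 10 of 45 cases, or 4 of 45 without the 12 h groups, with CDA2 at -2.16 and SPS4 at -1.77. By the rule 42 genes were higher and 121 lower. With IME1, LEU2 had values in wild type and none in kfc1, so genotype and this marker coincide there for amino acid genes.

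With IME1 overexpressed, kfc1 and wild type had far fewer genes 2-fold apart at 2 to 8 h than at 12 h. The nitrogen catabolite repression list had a median difference of -0.08 with 0 of 29 genes higher or lower, and the early meiotic list -0.09. At 12 h alone the early list differed by -0.53. The middle meiotic list had median differences between -0.10 and 0.01 at 2 to 8 h. Its median difference was -1.34 at 12 h, where its median was 1.22 in kfc1 and 3.03 in wild type. At 12 h NDT80 stood at 0.32 in kfc1 and 2.12 in wild type. Late sporulation genes, which act in spore wall maturation, had a median difference of -1.63 at 12 h, and cytosolic ribosomal protein genes -1.02. Stress response genes went the other way at 12 h (median difference 0.92, 18 of 38 at least 2-fold higher and none lower). The mitotic G1/S and budding genes were lower in kfc1 before that, with median differences of -0.49 at 4 h (9 of 32 at least 2-fold lower), -0.57 at 6 h (7) and -0.35 at 8 h (3). Averaged over time, the reductase gene GRE2 was 2.09 higher in kfc1, the alcohol dehydrogenase gene ADH2 1.73, CTT1 1.71 and the leucine gene LEU1 1.60, and PCL1 (-1.60), the cell wall gene CIS3 (-1.47) and the mannoprotein gene CWP2 (-1.32) were lower. In all, 20 genes were higher and 26 lower, a total of 46 that was 71 without the 2 h groups. The 12 h groups alone had 279 genes at least 2-fold higher and 300 lower, against 38 and 28 at 8 h. Wild type came from another series in this arm as well. The strains also differed in a leucine marker, since LEU2 stood between 6.87 and 7.91 in wild type and had no value in kfc1. The differences of LEU1 and other amino acid genes cannot be separated from that marker here.

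Over time with IME1, the early meiotic genes were higher in 30 of 35 cases in wild type (median 3.50) and 31 of 35 in kfc1 (median 3.70), with SAE3 at 7.33 and 7.15 and ECM11 at 5.97 and 5.95. PHO92, which encodes the m6A reader, was 5.50 and 6.45 above 0 h, and IME2 5.11 and 4.26. Unlike starts enter both, as PHO92 stood at -0.05 and -1.14 at 0 h and IME2 at -0.47 and 0.19. From 2 to 12 h the PHO92 ratio was slightly lower in kfc1 at each time point, with 6.19 and 5.88 at 12 h. Middle meiotic genes were higher in 21 of 45 cases in wild type and 12 of 45 in kfc1, with AMA1, an activator of the anaphase-promoting complex, at 3.32 and 4.14. Amino acid biosynthesis genes were higher in 46 of 54 and 31 of 53 cases, with ARG1 at 6.05 and 4.76, and nitrogen catabolite repression targets in 19 and 17 of 29. Stress response genes were lower in 23 and 11 of 38 cases, with GRE1 at -5.17 and -2.11. In wild type 1560 genes were higher and 819 lower (1296 and 1215 with columns centred on their mean), and in kfc1 630 and 324 (533 and 444).

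Much of the count over time in this arm depended on the start. From 0 h, cytosolic ribosomal protein genes were higher in wild type (133 of 139, median 1.84), as were ribosome biogenesis genes (62 of 65, median 1.82) and DNA replication genes (29 of 36, median 2.21), while in kfc1 the ribosomal protein list had a median of -0.06. With wild type without overexpression at 0 h as the start of wild type instead, the wild-type medians were -0.86 for ribosomal proteins, -0.13 for ribosome biogenesis and -0.0144 for ergosterol biosynthesis, which had been 1.04, and the wild-type count was 1002. For the difference between genotypes in the change over time, 269 genes were higher and 800 lower (368 and 656 with columns centred), with 128 of 139 ribosomal protein genes lower (median -1.87). With 0 h without overexpression of the same genotype as the start in both, that total of 1069 was 282, the ribosomal protein median -0.29, and the ribosome biogenesis median 0.19 in place of -1.34. The early meiotic list had a median difference of 0.01 in its change over time.

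Adding RIM4 to IME1 could be compared at 12 h, the only time after 0 h that both arms had, and the comparison looked at the later part of the programme. In wild type, 43 of 45 middle meiotic genes were higher with RIM4 (median 2.91), including the sporulation genes SPS4 (4.18), OSW1 (3.89) and SPS1 (3.87), and 11 of 16 late sporulation genes (median 2.96), including the glucoamylase gene SGA1 (3.69). NDT80 was 2.49 higher. In kfc1, 6 of 45 middle meiotic genes were higher (median 0.35), with SPS4 at 2.35 and SPO19 at 1.78, and 2 of 16 late genes, LDS1 (2.25) and LDS2 (1.30); NDT80 differed by 0.94. RIM4 itself was 0.51 higher in wild type and 1.74 in kfc1. Nitrogen catabolite repression targets were lower in 7 of 29 cases and higher in 2 in wild type, with PUT1, a proline oxidase gene, at -2.11, and higher in 13 of 29 in kfc1, with PTR2 at 2.70 and the urea transporter gene DUR3 at 2.06. Of the amino acid biosynthesis genes 21 of 53 were lower in wild type, with ARG1 at -4.41, and 1 of 53 in kfc1. In all, 585 genes were higher and 389 lower in wild type, and 134 and 177 in kfc1. The wild-type samples with IME1 alone were re-used from another series, whereas both arms of kfc1 belonged to this series. Wild type with IME1 alone also had URA3 at 7.50 and LEU2 at 7.30 at 12 h. Wild type with IME1 and RIM4 had no value for either marker then. Series and marker therefore cannot be separated from RIM4 in the wild-type numbers.

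The response to RIM4 at 12 h was lower in kfc1 for 44 of 45 middle meiotic genes (median -2.29), with PFS1, a spore formation gene, at -4.39 and SSP2 at -3.12, and for 11 of 16 late genes (median -1.79), with the spore wall transporter gene DTR1 at -3.40. It was higher for 17 of 29 nitrogen catabolite repression targets (median 1.15), with PUT1 at 4.03 and DAL5 at 3.70, and for 15 of 53 amino acid biosynthesis genes. It was lower for 6 of 37 autophagy genes, with ATG3 at -1.81, and for 12 of 31 TCA and glyoxylate cycle genes, with ACO1 at -1.89. By size alone, 377 genes were higher and 609 lower. In this difference the IME1 wild-type samples came from another series and the remaining ones did not.

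With IME1 and RIM4 both genotypes reached high levels of middle and late meiotic transcripts, at different sampled times. In wild type the middle meiotic list stood at 5.13 at 12 h, 4.68 at 24 h and 2.67 at 48 h, and in kfc1 at 1.99, 5.48 and 4.05, so the difference was -4.03 at 12 h, 0.45 at 24 h and 1.28 at 48 h. NDT80 followed the same order, at 4.61, 3.63 and 1.48 in wild type and 1.26, 4.07 and 2.71 in kfc1. The late sporulation list differed by -4.49 at 12 h, 0.35 at 24 h and 1.22 at 48 h. The early list was less apart, with differences of -0.83, 0.70 and 0.31. Because the sign changed, no middle or late gene met the rule across the 3 time points, while without the 12 h groups 16 of 45 middle genes were higher, and 5 of 16 late genes higher and 1 lower.

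**Figure D3:**
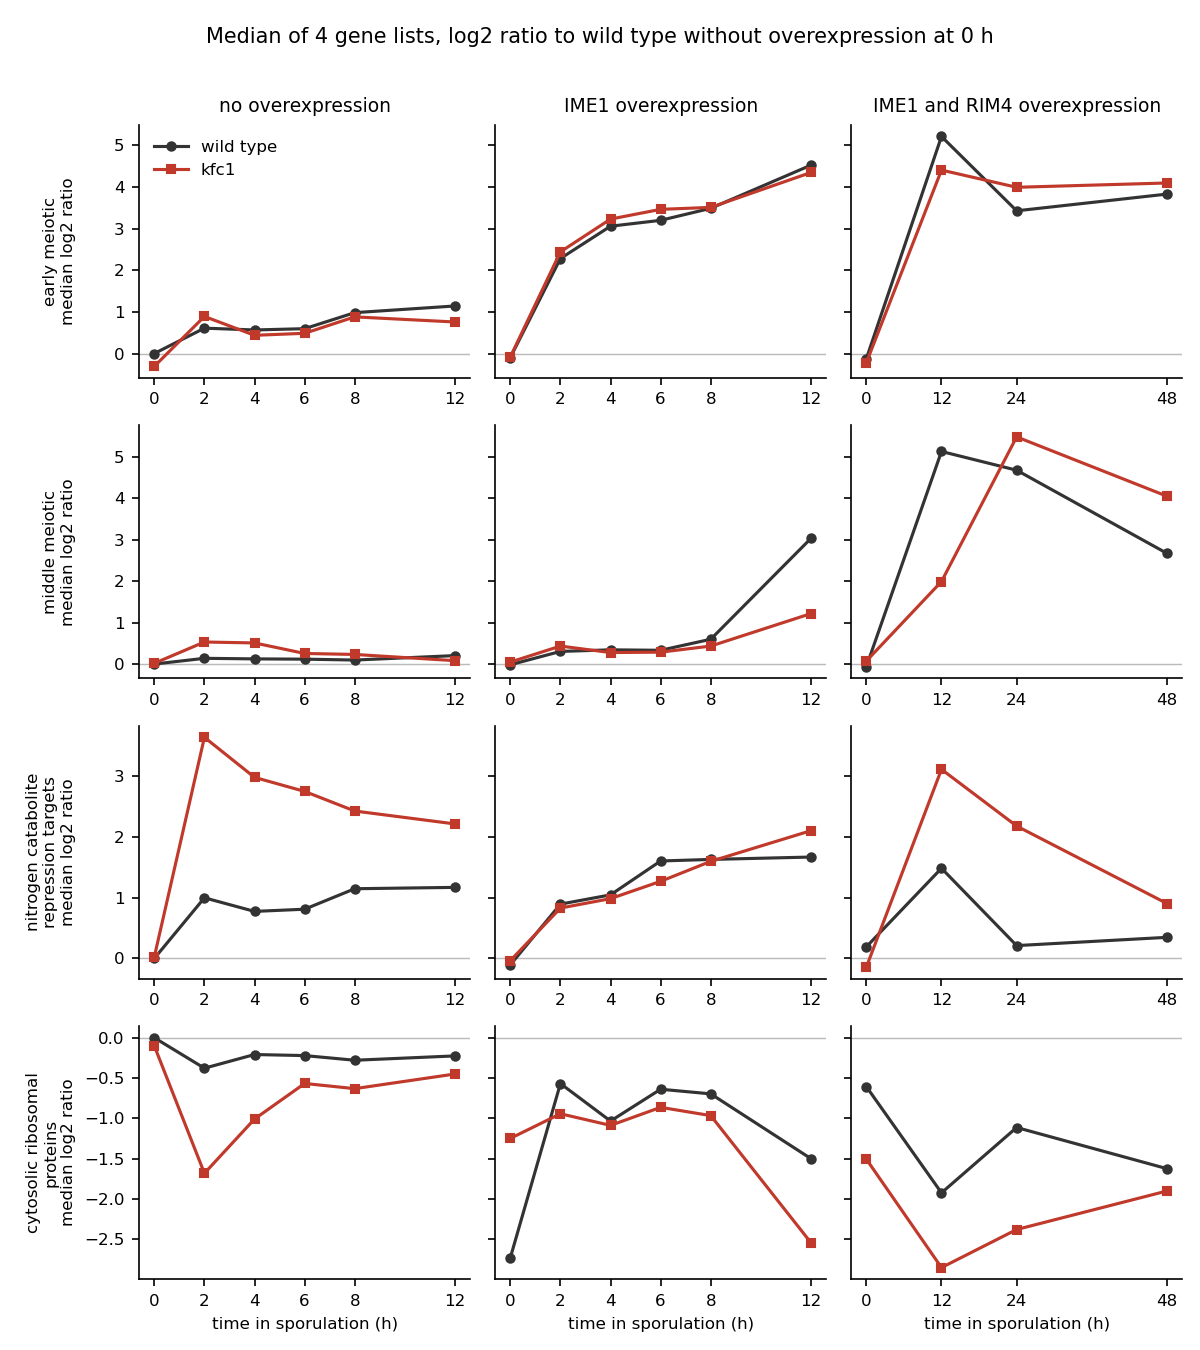
Median log2 ratio of 4 gene lists to wild type without overexpression at 0 h (vertical axes) against hours in sporulation, for wild type (circles) and kfc1 (squares) in the 3 overexpression arms. Middle meiotic genes reached 5.13 in wild type at 12 h and 5.48 in kfc1 at 24 h with IME1 and RIM4, and nitrogen catabolite repression targets were higher in kfc1 without overexpression and with IME1 and RIM4 but not with IME1 alone.

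Averaged over 12 to 48 h with IME1 and RIM4, nitrogen catabolite repression targets were again the list most raised in kfc1: 16 of 29 were higher and none lower (median 1.28), with PUT1 at 2.31 (0.65 to 3.92), MEP2 at 2.17 (0.85 to 3.80), GAP1 at 2.05 (0.43 to 3.47) and DAL80 at 2.02 (0.99 to 3.35). The list median differed by 1.50 at 12 h, 1.71 at 24 h and 0.31 at 48 h. Cytosolic ribosomal protein genes were lower in 28 of 139 cases (median -0.82), with RPS10A at -1.41 and RPS8A at -1.37, a count that was 12 without the 24 h groups and 81 without the 48 h groups. This list had already differed at 0 h in this arm, by -0.79 with 34 of 139 genes at least 2-fold lower. Its later differences were -0.85 at 12 h, -1.28 at 24 h and -0.36 at 48 h. The glyoxylate cycle gene MLS1 (-1.77), ADH2 (-1.67), the dihydroorotate dehydrogenase gene URA1 (-1.68) and the gluconeogenic gene FBP1 (-1.38) were lower too. In all, 97 genes were higher and 60 lower, a total of 157 that was 292 without the 12 h groups and 337 without the 48 h groups; without the same-sign rule 103 were higher and 104 lower. Both genotypes in this arm belonged to the same series. The strains differed in a marker, chosen for mention after its values were seen: URA3, the uracil biosynthesis gene, stood between 8.94 and 9.19 in kfc1 at 12 to 48 h and had a value in wild type at 24 h only (1.13). Genotype and this marker therefore coincided in this arm. The differences here, that of URA1 above all, cannot be separated from it.

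Genes higher in kfc1 without overexpression and genes higher in kfc1 with IME1 and RIM4 overlapped in 23 cases, where independent draws would share 1.38, and 14 of the 23 were nitrogen catabolite repression targets such as DAL80 and MEP2. Of the lower genes 7 were shared (0.222 by independent draws), VIR1 and URA1 among them, and 1 gene differed in opposite directions (1.22). The URA1 difference with IME1 and RIM4 cannot be separated from the URA3 marker. With IME1 alone, 2 higher and 2 lower genes were shared with the arm without overexpression (0.287 and 0.0963) and 4 went in opposite directions (0.447). With IME1 and RIM4 it shared 0 higher and 4 lower genes (0.296 and 0.240), and 5 went in opposite directions (0.569). Opposite pairs also exceeded independent draws there, so such draws are a low bar.

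Over time with IME1 and RIM4, 32 of 35 early meiotic genes were higher in each genotype (median 4.49 in wild type and 4.82 in kfc1), with MEI5 at 8.48 and 8.34, and 43 and 39 of 45 middle genes (median 4.25 and 3.80), with SPS4 at 8.78 and 8.82. Late sporulation genes were higher in 12 of 16 cases in each genotype, with LDS1 at 10.57 and 9.40. Respiratory chain and ATP synthase genes were lower in 25 and 27 of 33 cases, with ATP5 at -2.30 and -2.39, glycolysis and hexose transport genes in 15 and 13 of 27, with TDH1 at -5.20 and -4.72, and ribosomal protein genes in 59 and 66 of 139. In wild type 1009 genes were higher and 743 lower, and in kfc1 1328 and 861. With columns centred on their mean the split was 850 and 980 in wild type and 1088 and 1217 in kfc1. Between the genotypes, the change over time was higher in kfc1 for 21 of 29 nitrogen catabolite repression targets (median 1.69), with PTR2 at 5.18 (4.17 to 6.67) and DUR3 at 2.68, for 9 of 53 amino acid biosynthesis genes, with LEU1 at 2.07, and for 6 of 36 DNA replication genes, with POL1 at 1.24. These lists were lower in kfc1 at 0 h in this arm, with medians of -0.34, -0.22 and -0.45, and at 12 to 48 h the amino acid and DNA replication lists had genotype medians near 0 (-0.01 and 0.03, the former changing sign with columns centred), so a lower start enters their change. POL1 (-1.15) and LEU1 (-1.30) were lower at 0 h, and PTR2 more so, by the value given above, so its start enters its change too. By contrast MET17, a methionine synthesis gene whose change was 1.59 higher, was itself 1.35 higher at 12 to 48 h. The change over time was lower for 4 of 38 stress response genes, with HSP42 at -1.15, or 7 without the 12 h groups. In all, 254 genes were higher and 48 lower, a total of 302 that was 512 without the 12 h groups and 504 without the 48 h groups; without the same-sign rule 271 were higher and 99 lower.

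Of the named m6A genes other than VIR1, KAR4 was the one whose genotype difference was most apart between the arms without overexpression and with IME1: it was -0.33 without overexpression, 0.81 with IME1 and 0.83 with IME1 and RIM4, none of which reached the rule, and the first of these arms lay 1.14 below the second. KAR4 was already higher in kfc1 at 0 h with IME1 (0.55) and with IME1 and RIM4 (1.05). The difference was thus there in part at the start with IME1, and in full with IME1 and RIM4. RME1, a repressor of IME1, differed by 0.30, 0.90 and 0.37, and SLZ1, a subunit of the methyltransferase complex, by -0.46, -0.33 and -0.09. Haploid-specific and mating genes, fixed as a marker of haploid cells, had genotype medians of 0.14, -0.05 and 0.09, and ergosterol biosynthesis genes of -0.09, -0.16 and -0.06. The mitotic G1/S and budding genes, fixed as a marker of growing cells, had 0.22, -0.30 and 0.28. Cell wall and secretory genes had -0.05, -0.09 and -0.02, DNA replication genes -0.06, 0.01 and 0.03, and autophagy genes -0.05, 0.12 and -0.06. Ribosome biogenesis genes had -0.08, -0.17 and -0.27, and respiratory chain genes -0.08, -0.12 and -0.34. The list of meiotic entry regulators had medians of -0.01, -0.09 and 0.06. TCA and glyoxylate cycle genes had 0.29, 0.07 and -0.20, the m6A list -0.31, -0.12 and -0.16, and stress response genes -0.17, 0.34 and -0.13.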

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

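The genes below had a mean genotype difference of at least 2-fold, with the same sign at each time point, in 1 arm and the opposite way in another arm. The differences between arms were not tested, since there are no replicate values to test them with. Between the arms without overexpression and with IME1, ARG1, an arginine biosynthesis gene, went from 1.20 to -1.12, a shift of -2.32, and FIT2, a cell wall protein gene of iron uptake, from 1.11 to -1.13, a shift of -2.24. GRE1, a stress gene, went from -1.06 to 1.57 (2.64) and SPS100, a spore wall gene, from -1.30 to 1.13 (2.43). With IME1, LEU2 had values in wild type and none in kfc1, so the ARG1 shift cannot be separated from that marker. Between the arm without overexpression and the arm with IME1 and RIM4, the hexose transporter gene HXT2 went from -1.01 to 1.29, a shift of 2.30.

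Between IME1 alone and IME1 with RIM4, ADH2 went from 1.73 to -1.67 (-3.40), GRE1 from 1.57 to -1.96 (-3.54), RGI2, a gene of respiratory growth, from 1.22 to -1.10 (-2.32), SPG1, a stationary phase gene, from 1.22 to -1.30 (-2.51), and SCW10, a cell wall glucanase gene, from -1.25 to 1.16 (2.41). These 2 arms also differ in the hours sampled and, for wild type, in the series of origin and in the markers URA3 and LEU2.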

How the results depend on the processing

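All alternatives given here were chosen after the results had been seen. The planned ones (another pseudocount, other filters on low values, quantile and TMM normalization, replicate blocks, a fit of fewer groups, read counts recovered from the values, leaving out each replicate, and an estimated correlation for gene lists) were not run, since the table holds combined ratios without replicates or levels. No paired analysis was possible because the replicates of a condition had been combined before deposition. The total counts of all 21 comparisons stayed within 1.5 times with columns centred on their mean, with RefSeq genes only and with genes of few reads left out, and the totals of the 15 comparisons over several time points did so without the same-sign rule. The split did not in the arm with IME1 and RIM4, where without that rule the lower genes went from 60 to 104 for kfc1 against wild type and from 48 to 99 for the genotype difference over time.

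With the kfc1 columns as deposited, the count of kfc1 against wild type without overexpression was 249, that over time in kfc1 1257, that of the genotype difference over time 804 and that of IME1 overexpression in kfc1 837; this follows from the reference, since kfc1 at 0 h then enters once too often or not at all. The genotype differences of GRE1 and FIT2 without overexpression changed sign to 0.64 and -0.0396 in the same way. With 0 h without overexpression of the same genotype as the start of the IME1 arm, the count over time was 1002 in wild type and that of the genotype difference 282; the wild-type medians changed sign to -0.86 for ribosomal proteins, -0.13 for ribosome biogenesis and -0.0144 for ergosterol, and the genotype difference to 0.19 for ribosome biogenesis but not for ribosomal proteins (-0.29). When the start was replaced in wild type alone, the genotype difference set unlike starts against each other and gave 469 genes and medians of 0.89 for ribosomal proteins and 0.72 for ribosome biogenesis, which hold the 0 h offset of kfc1 with IME1 (-1.25 and -0.84).

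Leaving out a time point raised several counts, and the cause was not tested: kfc1 against wild type gave 177 genes without 12 h in the arm without overexpression, 71 without 2 h with IME1, and 292 without 12 h or 337 without 48 h with IME1 and RIM4, where the genotype difference over time gave 512 and 504. Without replicates, a difference near 2-fold cannot be separated from noise, and genes with few reads are the least certain.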

Other observations

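The tests in the paragraphs on VIR1, on the wild-type IME1 group at 0 h and on middle gene timing were chosen after the results had been seen. Haploid-specific and mating genes were higher over time with IME1 and RIM4 in both genotypes, 15 of 24 in each (median 1.50 in wild type and 1.43 in kfc1), with STE18, the G protein gamma subunit gene, at 4.84 and 3.78 and NEJ1, a regulator of end joining, at 4.65 and 4.08. YPR203W, near a chromosome end, was lower with RIM4 than with IME1 alone at 12 h (-3.86 in wild type and -3.39 in kfc1), as was YLR256W-A, a transposon gene (-3.58 and -3.78). RPL1A and RPL1B, paralogs that encode the same ribosomal protein, were lower with RIM4 in both genotypes too, RPL1A at -2.95 and -2.29 and RPL1B at -2.68 and -2.31.

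Marker genes differed between the strains. LEU2 had values between 6.87 and 7.91 in wild type with IME1 and no value in kfc1 with IME1 or in either genotype with IME1 and RIM4. URA3 stood between 6.90 and 7.94 in wild type with IME1, between 4.47 and 8.25 in kfc1 with IME1 and between 5.77 and 9.19 in kfc1 with IME1 and RIM4. Without overexpression URA3 lay between -0.06 and 0.04 wherever it had a value, in wild type and kfc1 alike. In wild type it had no value at 2 to 8 h, and its 0.04 at 12 h was the smallest value of genes without reads in the reference. These ratios therefore rest on few reads and do not show an expressed, unchanged gene. LEU2 was likewise blank there or near 0, with 0.03 in wild type at 8 h. These genes were chosen after their values were seen.

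The deleted gene VIR1 read near wild type in the deposited kfc1 values without overexpression at 2 to 12 h. A ratio to kfc1 at 0 h is the candidate explanation that other genes bear out: 31 values of genes without reads at wild-type 0 h were negative in these 5 columns, and none in the columns of the other arms. Given that reference, libraries of a wild-type strain would read above 5 for VIR1, and the mean was 0.60. VIR1 alone would not exclude them, since wild-type libraries set against wild type at 0 h read much the same (0.33 to 0.82).

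The wild-type IME1 group at 0 h stood apart from the other groups at 0 h. Early action of IME1 is argued against by the early meiotic list, whose median was -0.10, although the IME1 transcript stood at 1.94. Single meiotic genes varied in that group, with SLZ1 at 1.56, IME4 at 0.90, RIM4 at 0.70 and IME2 at -0.47, so the argument covers the list as a set. A single scaling factor is argued against by list medians that spread over 3.20, from autophagy at 0.47 to ribosomal proteins at -2.73. Series of origin stays open: the 4 other groups at 0 h, set against re-used wild type across series, had spreads over genes of 0.344 to 0.675, short of 0.937, but they differ in genotype or arm, and the IME1 group and its reference were both re-used. A difference in how the culture had grown before 0 h may remain too; no biological explanation was tested.

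Middle genes were lower in kfc1 with IME1 and RIM4 at 12 h and not at 24 or 48 h. The median difference of 0.45 at 24 h restates that the loss did not last and is not a separate test of it. List medians of the genotype difference spread over 5.9965 at 12 h, from late sporulation genes at -4.49 to nitrogen catabolite repression targets at 1.50. That spread argues against a single scaling factor of a 12 h column. For the middle genes a later course is consistent with the kfc1 median at 24 h, 0.35 above the highest wild-type median, but over all genes kfc1 at 24 h correlated no better with wild type at 12 h (0.900) than at 24 h (0.921, a difference of -0.0217), and kfc1 at 12 h correlated best with wild type at 48 h (0.850). Whether the whole course ran later therefore stays open, and fewer cells at the middle stage cannot be told apart from later cells by the kfc1 median of 1.99 at 12 h, since bulk RNA averages over cells. A delay of the middle genes in kfc1 may be part of the pattern, a hypothesis found and examined on the same data.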
